A study of Homo sapiens with 7 samples.

How the data were processed

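ATAC-seq libraries were made from LUHMES-derived neurons treated with antimycin A and oligomycin (4 libraries) or with vehicle (3 libraries). Nuclei were isolated by detergent lysis and tagged with Tn5 transposase, and the DNA was amplified by PCR, per the labels' protocols. FastQC, Bowtie2, Picard and the genome build hg38 are named in the submitters' processing notes, without versions. Peaks were called with MACS2, per the file headers, separately for each library and not on pooled samples. Whether reads were shifted for the Tn5 offset, and the caller's settings, are not given in the sources used here. A shift of a few base pairs is small beside the regions, but the settings of the caller would change region width and number.

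Each deposited list gives, for each peak, its position, a score, the fold enrichment at the summit over background as a ratio, and the −log10 p-value and −log10 q-value, all as the authors' peak caller computed them. The deposited q-values all lie below 0.05. These values belong to single peaks of single libraries, so they were used mainly to rank or filter regions within a list. Across libraries they served in the ranks of named genes and distal regions, by the lowest −log10 p, and as enrichment over the recovered background, in the signal contrast, the equal-enrichment lists and the SLC7A5 locus. The deposited fold enrichments of each library lie on a grid of (pileup + 1) divided by (background + 1) with 1 constant background per library. With a tolerance of 0.02, 100% of the folds gave a whole summit pileup in each library, so the background could be recovered as a measure of relative depth. The total number of reads is not given in the sources used here.

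Peaks on chromosomes 1 to 22 and X were kept, which left out 29 to 54 peaks per library, and peaks that share a position were merged within a library. The shortest list (vehicle 7) held 32828 regions, and equal-size lists were made from the 32828 regions of largest −log10 p in each library. Ties at that limit, 1133 to 9516 regions per library, were ordered by fold enrichment, width and position. The weakest region of an equal-size list had a −log10 p of 21.0 in stressed 7 and 4.37 in vehicle 7.

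No genome sequence was used here. Gene positions came from a table of RefSeq genes on GRCh38.p14, the build of the files, with 19974 protein-coding genes on the chromosomes kept. The table gives the ends of a gene and no strand, so the planned promoter window became a window of 1000 bp around either end of a gene, and the nearest gene was the one with the nearest end, within 100 kb for the gene lists. The text therefore speaks of gene ends, which can be the start or the end of transcription. The content of 28 DNA motifs, planned for distal regions, and GC content were not analysed here. Coordinates are 1-based on hg38.

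Before the data were examined, 19 gene lists with 376 genes, the tests, most alternatives and the rule for named genes were fixed, and all 376 genes matched the table. The lists covered the integrated stress response, mitochondrial proteostasis, mitophagy, Parkinson disease genes, oxidative stress, glycolysis and hypoxia, immediate early genes, the unfolded protein response, heat shock, p53 and apoptosis, mitochondrial biogenesis and respiration, autophagy and lysosome, innate and inflammatory genes, and markers of dopaminergic neurons, all neurons, progenitors, other neurons, glia, and mesenchymal and endothelial cells. The rule named a panel of 20 stress and dopaminergic genes, list genes with a gene-end region in at least 3 stressed and 0 vehicle libraries or in 0 stressed and at least 2 vehicle libraries, the 10 strongest other genes and the 10 strongest distal regions per direction that were present in all libraries of one treatment and none of the other, and list genes nearest to such a distal region. Other list members were named as examples after their values were seen. Some genes that the rule names are not reported here.

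Values per library were compared by an exact permutation test over all 35 assignments of the 7 labels, two-sided on the absolute difference of means, with a smallest possible p of 0.0286. P-values of the gene lists were adjusted by the Benjamini-Hochberg method over the 19 lists of each family. Consensus regions were the merged union of the equal-size lists, with presence defined as an overlap of at least 1 bp, and each was tested with Fisher's exact test. The gain of each list was also ranked among 10000 random lists matched, gene by gene, on the number of libraries with a region at an end in the equal-size, deposited and shorter equal lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

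The overlap functions were tested on simulated data against bedtools 2.31.1 and gave equal results. The comparison of stressed with vehicle libraries was tested on 159902 simulated regions drawn at the depth of each library. With no change simulated, 182 regions were called stressed-only and 143 vehicle-only, and the genes with a region at an end differed by 234 (exact permutation p = 0.171). Of 200 regions ranked just below the equal-size list and raised in the stressed libraries, 19.0% were recovered at 2-fold, 56.0% at 4-fold and 54.0% at 8-fold, so the comparison misses many regions that change.

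Alternatives included the lists as deposited, a threshold of 5 on −log10 q, equal lists of 16414 regions, ranking by fold enrichment, a window of 2500 bp, a distance of 20 kb, an overlap of 50%, counting shared regions, leaving out each library, and the differentiation number as a block. Windows of 100 bp on each side of summits, an enrichment of at least 8.18 over background in each library in place of equal list size, the better supported gene end, background or signal contrast as a covariate, and the short or long lists alone were added after seeing the data.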

Results

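Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in neurons derived from LUHMES, an established human mesencephalic cell line that was differentiated for 6 days into cells labelled as dopaminergic neurons. The cells received antimycin A at 25 µM, an inhibitor of respiratory complex III, together with oligomycin at 10 µM, an inhibitor of the mitochondrial ATP synthase, for 8 hours. The 4 treated libraries, called stressed from here on, came from differentiations 6, 7, 8 and 9. The 3 vehicle libraries received DMSO and came from differentiations 6, 7 and 8. The labels describe the differentiations as independent batches of cells. The study asked which chromatin regions are open under mitochondrial stress and in the control condition.

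The 7 lists of accessible regions differed mostly in length. They held 188516, 248900, 55533 and 53063 regions in stressed libraries 6, 7, 8 and 9, and 53398, 32828 and 159902 regions in vehicle libraries 6, 7 and 8. The regions spanned 77.5 ± 60.6 Mb in the stressed libraries (SD, n = 4) and 39.8 ± 34.0 Mb in the vehicle libraries (SD, n = 3), with an exact permutation p of 0.400. The number of regions differed by 0.73 on the log2 scale (exact permutation p = 0.457, two-sided), and the median region width was 380.2 ± 89.1 bp against 328.0 ± 9.54 bp (exact permutation p = 0.429, n = 4 and 3). None of these differences passed the exact permutation test, and in span and width each was smaller than the SD of the stressed libraries but larger than that of the vehicle libraries. The genome background implied by the fold enrichments, a measure of relative depth, ranged from 0.816 to 5.99 fragments in the stressed libraries and from 0.492 to 1.43 in the vehicle libraries. Because a longer list holds more weak regions, the comparisons that follow use the 32828 strongest regions of each library, which is the length of the shortest list. A region outside this selection ranked lower within its own library and was not necessarily closed.

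The stressed libraries had more of their strongest regions at the ends of protein-coding genes. Of the equal-size lists, 35.4% ± 0.845 of regions lay within 1 kb of a gene end in the stressed libraries (SD, n = 4) and 32.3% ± 1.52 in the vehicle libraries (SD, n = 3), and each stressed library lay above each vehicle library. These regions marked 12464 ± 383 genes in the stressed libraries and 11203 ± 513 in the vehicle libraries, a difference of 1260 genes. Both differences had an exact permutation p of 0.0286 (two-sided, n = 4 and 3), the smallest that 35 assignments of the labels allow. Lists of equal number still differed in region width. The median width was 916, 1450, 484 and 740 bp in stressed libraries 6, 7, 8 and 9. In vehicle libraries 6, 7 and 8 it was 475, 319 and 868 bp. Wider regions can reach more gene ends, so width enters both measures. Of 14055 genes with a region at an end in at least 1 library, 3862 had one in a larger share of the stressed libraries and 910 in a larger share of the vehicle libraries. When regions were chosen at an equal enrichment over background, the difference in genes was 276 (exact permutation p = 0.771) and that in the share 9.92 percentage points (exact permutation p = 0.200). From 3.13 percentage points, the share difference went to 3.12 with windows of 2500 bp around gene ends (exact permutation p = 0.143), 2.38 with windows of 100 bp on each side of the summits (p = 0.0857), and 2.97 with log2 background (p = 0.0857) or 2.37 with log2 signal contrast (p = 0.143) as a covariate, where contrast is the median enrichment of the 5000 strongest regions over background. The gene difference was 741 with background (exact permutation p = 0.0286) and 1318 with contrast as a covariate (exact permutation p = 0.114), and 1904 in the lists as deposited (exact permutation p = 0.229). In the lists as deposited, the share at gene ends was 17.1% ± 9.55 against 22.2% ± 11.3 (n = 4 and 3), the opposite direction, with an exact permutation p of 0.6.

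**Figure D1:**
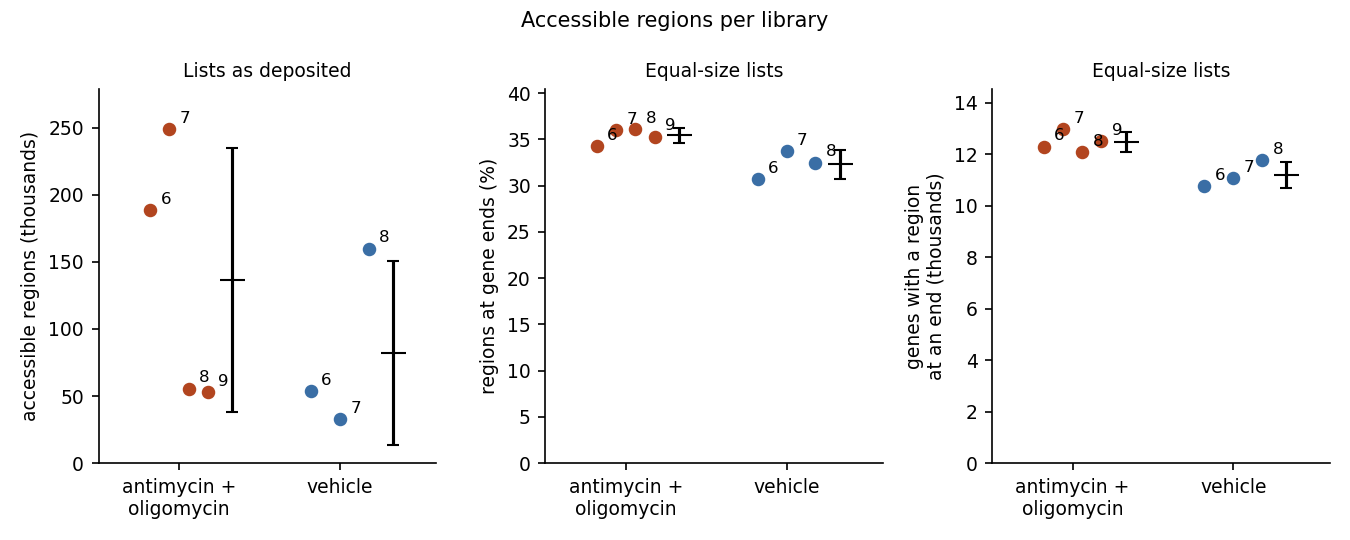
Points are libraries, numbered by differentiation, and bars are the mean and SD (n = 4 and 3); the vertical axes give the number of regions as deposited, the percent of the equal-size list at gene ends, and the number of genes with a region at an end. The deposited lists overlap between treatments, while in the equal-size lists the stressed libraries lie above the vehicle libraries in both measures.

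All 19 gene lists had on average more members with an accessible end in the stressed libraries, and no list passed the correction over 19 lists. Genes as a whole moved the same way, from 11203 with a region at an end in the vehicle libraries to 12464 in the stressed libraries. For the integrated stress response, the ATF4-driven program of amino acid supply and protein synthesis control, 28.5 ± 0.577 of 32 genes had a region at an end in the stressed libraries (SD, n = 4) against 25.3 ± 0.577 in the vehicle libraries (SD, n = 3). STC2, which encodes a secreted glycoprotein, had such a region in 4 of 4 stressed and 0 of 3 vehicle libraries. The cystine transporter gene SLC7A11 had it in 4 and 1, the amino acid transporter gene SLC7A5 in 3 and 1, and CEBPB, SHMT2 and PPP1R15A each in 4 and 2. In the deposited lists CEBPB and PPP1R15A had a region at an end in 4 stressed and 3 vehicle libraries, and SHMT2 in 4 and 2. At the SLC7A5 end, vehicle 8 had an enrichment over background of 11.9, outside its equal-size list. Stressed 7 (11.2) and stressed 9 (8.01) had lower enrichments there, within theirs. In the list of oxidative stress genes, all 20 members had a region at an end in each stressed library against 16.7 ± 1.15 in the vehicle libraries, and 6 members, including SLC7A11, which both lists hold, were open in a larger share of the stressed libraries. These were TXNRD1 (4 and 0), which encodes a thioredoxin reductase, FTL and SLC7A11 (4 and 1 each), and HMOX1, KEAP1 and SRXN1 (4 and 2 each).

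Of the other gene groups, the list of p53 and apoptosis genes had 16.2 ± 0.5 of 20 genes against 14.7 ± 0.577, with the death receptor gene TNFRSF10B open in 3 and 0 libraries, GADD45B in 2 and 0, and BBC3 in 1 and 0. Markers of mesenchymal and endothelial cells, which are not the labelled cell type, moved with these groups: 5.75 ± 0.5 of 13 against 3.67 ± 0.577, through PDGFRB (4 and 0), COL1A1 (3 and 0) and PRRX1 (4 and 2). In the deposited lists PDGFRB had a region at an end in 4 and 2 libraries, COL1A1 in 3 and 1, and PRRX1 in 4 and 2. These 4 lists, of 19, reached an unadjusted exact permutation p of 0.0286 (two-sided, n = 4 and 3), and their Benjamini-Hochberg adjusted p was 0.136, so no list passed the correction. Against 10000 random lists of genes open in as many libraries, the gain of the integrated stress response list stood at percentile 77.2, oxidative stress at 94.2, p53 and apoptosis at 76.3, and the mesenchymal and endothelial markers at 95.9. The gains of these lists, in that order, were 3.17, 3.33, 1.58 and 2.08 genes. The median gains of their matched random lists were 2.58, 2.17, 1 and 0.917 genes. In the lists as deposited, with −log10 q of at least 5 and at equal enrichment over background, 0 lists reached the unadjusted threshold. In equal lists of 16414 regions the gain was 6.83 genes for the integrated stress response, and the mesenchymal and endothelial list changed direction to -0.167. The gain over all genes in those lists is not reported here.

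Mitophagy genes showed 18.8 ± 0.5 of 20 open ends in the stressed libraries against 16.7 ± 1.15 (exact permutation p = 0.0571, n = 4 and 3). PINK1, the kinase that marks damaged mitochondria, was open at an end in 3 and 0 libraries, MUL1 in 4 and 1, and SQSTM1 and RHOT1 in 4 and 2. In the deposited lists PINK1 had a region at an end in 4 stressed and 2 vehicle libraries, RHOT1 in 4 and 3 and MUL1 in 4 and 1. The immediate early genes had 22.2 ± 0.957 of 26 against 19.7 ± 1.53 (exact permutation p = 0.0857, n = 4 and 3), with FOSL1 and NR4A1 open in 4 and 1 libraries and FOS and EGR1 in all 7. In the deposited lists NR4A1 had a region at an end in 4 stressed and 3 vehicle libraries, and FOSL1 in 4 and 1. With windows of 100 bp on each side of summits, FOSL1 had a region at an end in 0 stressed and 0 vehicle libraries. An exact permutation p of 0.0857 was also obtained for glycolysis and hypoxia genes (21.8 against 20 of 26), heat shock genes (12.5 against 11 of 17), genes of mitochondrial biogenesis and respiration (27.0 against 25.0 of 28) and markers of other neurons (7.75 against 6.33 of 13). Genes of the unfolded protein response of the endoplasmic reticulum (18.0 against 17.3 of 19) and innate and inflammatory genes (12 against 10.7 of 22) had an exact permutation p of 0.143. For Parkinson disease genes (17.2 against 16 of 18) it was 0.200, for mitochondrial proteostasis (15.5 against 14.7 of 16) 0.400, and for autophagy and lysosome genes (23.5 against 22.3 of 25) 0.571.

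The lists of neuronal identity markers did not pass the exact permutation test. Dopaminergic markers had 12 of 19 genes with an open end in each stressed library and 11.7 ± 0.577 in the vehicle libraries (exact permutation p = 0.429, n = 4 and 3). NR4A2, a transcription factor of dopaminergic neurons, was open in all 7 libraries and the dopamine transporter gene SLC6A3 in 4 and 2. The ends of TH, which encodes the rate-limiting enzyme of dopamine synthesis, and of the vesicular transporter gene SLC18A2 were not among the strongest regions of any library. In the deposited lists TH had a region at an end in 3 stressed and 0 vehicle libraries, and SLC18A2 in 4 and 1. Pan-neuronal markers (17.5 against 16.3 of 19, p = 0.543), progenitor and proliferation markers (13.5 against 11.3 of 16, p = 0.171) and glial markers (6.75 against 4.67 of 16, p = 0.286) did not pass the exact permutation test either.

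**Figure D2:**
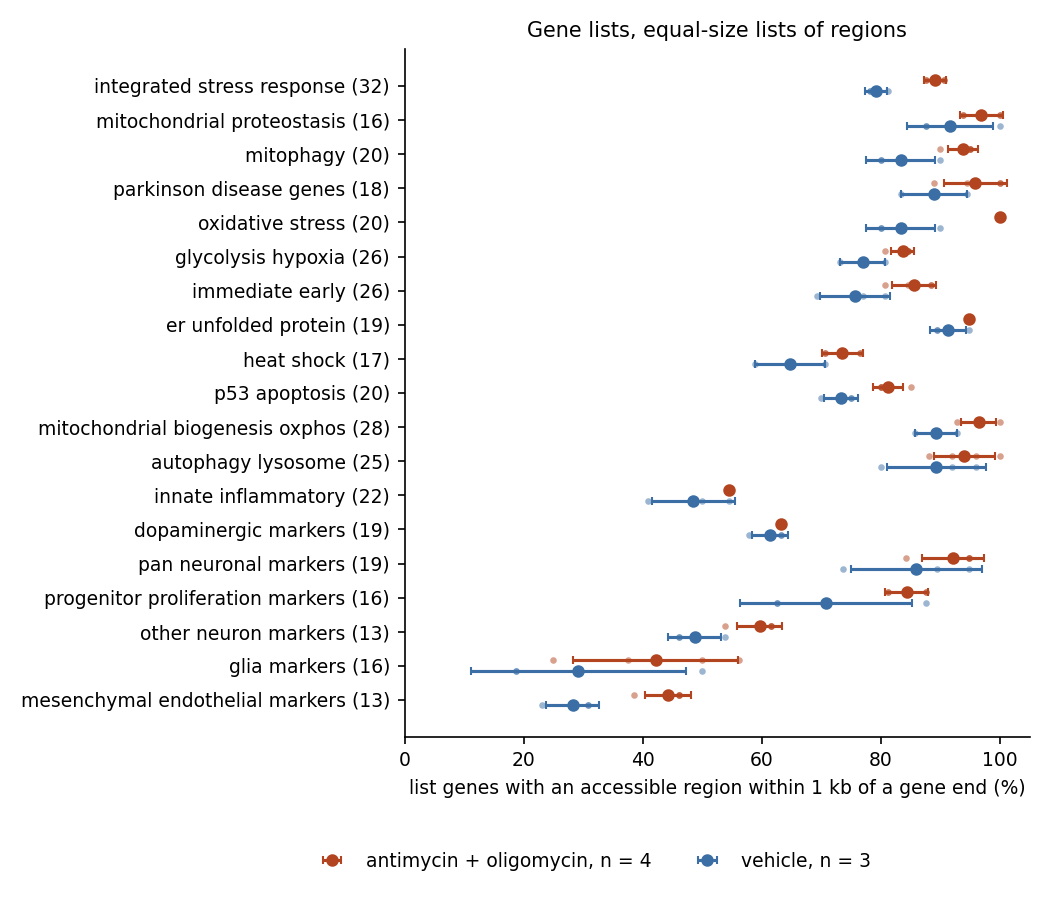
The horizontal axis gives the percent of each list's genes with an accessible region within 1 kb of a gene end in the equal-size lists, and the number of genes stands in brackets; large points and bars are means and SD of 4 stressed and 3 vehicle libraries, and small points are libraries. The integrated stress response stood at 28.5 of 32 genes against 25.3, and dopaminergic markers at 12 of 19 against 11.7.

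Most of the classical stress genes were open in both conditions. DDIT3, ATF4, TRIB3, CHAC1, DDIT4, SESN2 and GDF15, genes of the integrated stress response, had a region at an end in all 4 stressed and all 3 vehicle libraries. ASNS, which encodes asparagine synthetase, was open in 3 and 2. The ends of ATF3 and FGF21 were not among the strongest regions of any library.

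Distal regions near the gene lists were compared as their number per 1000 distal regions. Regions whose nearest gene belonged to the integrated stress response numbered 1.45 ± 0.121 in the stressed and 1.01 ± 0.313 in the vehicle libraries. Those nearest to immediate early genes numbered 2.69 ± 0.269 and 2.13 ± 0.186. Both had an exact permutation p of 0.0571 (two-sided, n = 4 and 3) and an adjusted p of 0.543. Regions nearest to dopaminergic markers numbered 3.02 ± 0.252 and 2.73 ± 0.260 (exact permutation p = 0.229, n = 4 and 3). The remaining 16 lists had an exact permutation p of 0.143 or more.

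Regions that separated the treatments completely were few. The equal-size lists merged into 62514 consensus regions, of which 14330 were present in all 7 libraries, 488 in 4 of 4 stressed and 0 of 3 vehicle libraries, and 231 in 0 of 4 and 3 of 3. The stressed-only regions lay at a gene end in 143 cases (29.3%) and the vehicle-only regions in 7 (3.03%). The odds ratio was 13.3 (Fisher's exact test across regions, p = 2.22e-19), but regions are not independent replicates. Region width was not matched in this test, and a wider region reaches a gene end more easily. The stressed-only regions named below were 769 to 4814 bp wide and the vehicle-only ones 410 to 1320 bp. Of all consensus regions, 21.8% lay at a gene end. At the level of genes, 115 had a region at an end in all stressed libraries and no vehicle library, and 3 the reverse. At equal enrichment over background these counts were 5 and 6, and 46 regions were stressed-only. Setting stressed 6, stressed 7, stressed 9 and vehicle 8 against the other libraries gave 111 and 2 genes, so such a skew is not particular to treatment. By Fisher's exact test per region, 719 regions had an unadjusted p of 0.0286 and 0 passed the Benjamini-Hochberg correction, because 4 against 3 libraries cannot give a smaller p. In the deposited lists 23 of the 488 stressed-only regions overlapped no vehicle region, 357 overlapped a region of vehicle 8 alone, and 1 of the 231 vehicle-only regions overlapped no stressed region.

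Stressed-only regions marked genes of the integrated stress response at 4 loci. SLC7A5 (chromosome 16, 87830023 to 87869507, hg38) held 3 within its gene body, at 87843516 to 87845284, 87852304 to 87854708 and 87860289 to 87861582. The region of STC2 was at chromosome 5, 173326623 to 173330355, over a gene end. PSAT1, which encodes an enzyme of serine synthesis, had one at chromosome 9, 78291278 to 78292463, which was 4662 bp from a gene end, and ATF5 one at chromosome 19, 49923516 to 49924924, within the bodies of IL4I1 and NUP62. In its deposited list, vehicle library 8 held regions over 2 of the 3 SLC7A5 positions, with enrichments over background of 13.3 and 12.6; they fell outside its equal-size list, yet stressed 7 (10.7 and 11.2) and stressed 9 (10.7 and 8.01) had lower enrichments there. Oxidative stress genes had 3 stressed-only regions, at TXNRD1 (chromosome 12, 104215468 to 104216236, a gene end), SRXN1 (chromosome 20, 642490 to 643614) and FTH1, the ferritin heavy chain gene (chromosome 11, 61971518 to 61972738).

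**Figure D3:**
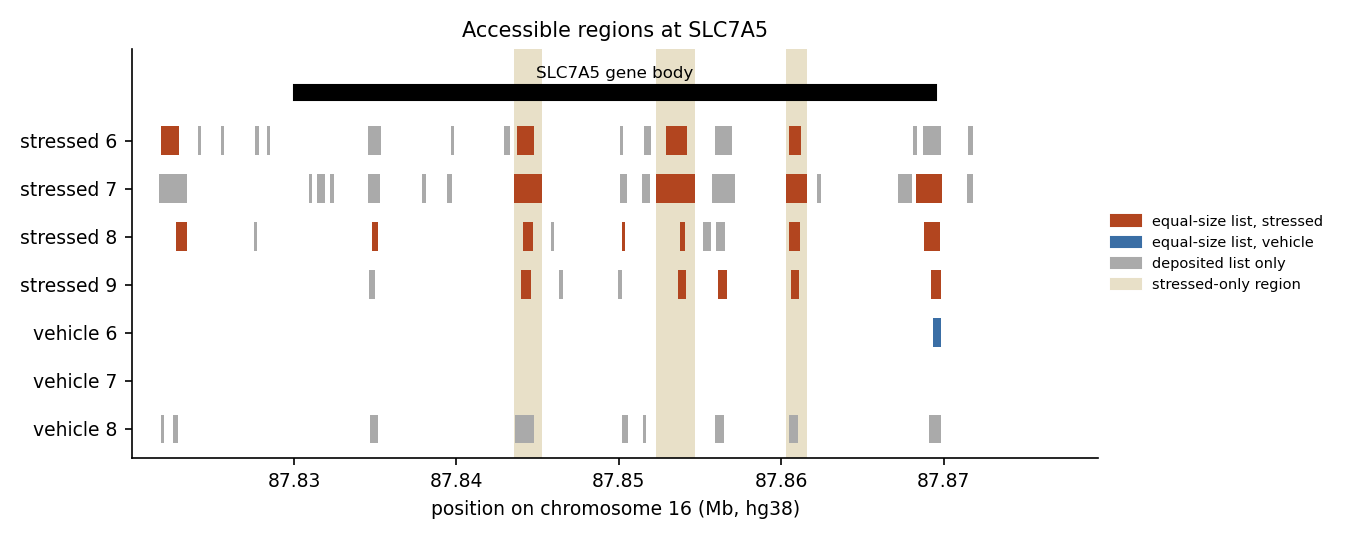
The horizontal axis is the position on chromosome 16 in Mb (hg38), each line is 1 library, coloured boxes are regions of the equal-size lists, grey boxes are regions of the deposited lists only, and shaded bands are the 3 stressed-only regions. The bands hold a coloured box in each of the 4 stressed libraries and in none of the 3 vehicle libraries, and vehicle 8 has grey boxes in 2 of them.

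Further list genes with a stressed-only distal region nearest to them included the dopaminergic markers DDC and RET, the immediate early gene ARC, the interferon regulatory factor gene IRF1, the lysosomal protease gene CTSD, HERPUD1 of the unfolded protein response and the neuronal marker RBFOX3. The only vehicle-only region nearest to a list gene lay 68344 bp from the glial marker AQP4. Ranked by their weakest stressed library, the strongest distal stressed-only regions included those nearest to RPL27A (chromosome 11, 8657123 to 8659229, within TRIM66), UNC5B, a netrin receptor gene (chromosome 10, 71265368 to 71267424, within the gene), C19orf12 (chromosome 19, 29687062 to 29688857), VEGFA, OTOS, EEF2K, SLX4IP, SPMIP1 and PSTPIP1. The regions nearest to VEGFA and OTOS lay 139589 and 109984 bp from a gene end, beyond the distance limit of the gene lists. VEGFA belongs to the glycolysis and hypoxia list, but its region was therefore not counted there. The strongest vehicle-only regions lay nearest to NMBR (chromosome 6, 142038827 to 142039479), the glutamate receptor gene GRIK2 (chromosome 6, 102035274 to 102035831, within the gene), NDN, FAM98A, CALCRL, IGSF11, SAMD12, the amyloid precursor gene APP (chromosome 21, 26107493 to 26108018, within the gene), TTC29 and GALNTL6. Those of FAM98A, GALNTL6, IGSF11, NDN and TTC29 lay 662004, 551220, 155665, 110308 and 104077 bp from a gene end. These distances also exceeded the limit, although the GALNTL6 region lay within the gene. Outside the lists, genes were ranked by the lowest, over the libraries, of the best −log10 p at either end, which different regions can supply in different libraries. The 10 highest stressed-only genes, cut within a tie of 6 genes, were COL15A1, FAM110D, FEZF1, GRB2, MLST8, MRPS2, PGPEP1, PIERCE1, SNRPC and TTLL12. The genes MRPS2 and PIERCE1 are neighbours on chromosome 9. The 3 vehicle-only gene ends were those of CHRNA10, MS4A10 and CDH8.

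Libraries of one treatment were not found to resemble each other more than libraries of different treatments. The mean Jaccard index of the equal-size lists, the share of covered base pairs that 2 libraries had in common, was 0.463 among stressed libraries, 0.385 among vehicle libraries and 0.409 between treatments. The difference of within-treatment and between-treatment means was 0.0275 (exact permutation p = 0.486, two-sided, n = 4 and 3). The 3 libraries with the longest deposited lists, stressed 6, stressed 7 and vehicle 8, had a mean index of 0.578 among themselves. Their equal-size lists also spanned the most, 35.8, 55.2 and 33.9 Mb, against 14.9 to 29.9 Mb in the others.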

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

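In 6 of 49 measures checked, 1 of the 4 stressed libraries stood apart from the others by more than Dixon's limit. All 6 are whole-number counts of list genes with a region at an end in which the other 3 libraries tied, so a difference of 1 or 2 genes was enough. The chance rate of about 1 in 20 holds for continuous values and does not apply to such counts. Stressed 9 had 18 mitophagy genes (the others 19), 17 p53 and apoptosis genes (the others 16) and 7 markers of other neurons (the others 8). Stressed 8 had 21 glycolysis and hypoxia genes (the others 22), 16 pan-neuronal markers (the others 18) and 5 mesenchymal and endothelial markers (the others 6).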

How the results depend on the processing

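The differences in region number, span and width kept their direction and stayed short of the threshold under all settings run, and the 7 libraries, the depth and the shortest list limit what can be seen. Ranking by fold enrichment and the overlap of 50% changed nothing by construction, and the motif alternatives were not run. The summit windows, equal enrichment, better supported gene end, covariates and the short and long lists alone were added after seeing the data. Where no reason is given below, the cause was not tested. In the lists as deposited the share at gene ends reversed to -5.09 percentage points and the gene difference was 1904 (exact p = 0.229), the similarity difference was -0.00505, stressed-only and vehicle-only regions numbered 296 and 11, such genes 22 and 0, and 0 lists passed the unadjusted threshold at gene ends. With −log10 q of at least 5 the corresponding values were -5.06, 2240 (exact p = 0.286), -0.0203, 33 and 0, 1 and 0, and 0 lists. Equal lists of 16414 regions gave 244 stressed-only regions, 1 list in distal regions and a reversed mesenchymal and endothelial difference of -0.167. The window of 2500 bp gave a share difference of 3.12 (exact p = 0.143), and a nearest gene within 20 kb gave 2 lists in distal regions. Windows of 100 bp on each side of summits gave a share difference of 2.38 (exact p = 0.0857) and 5 vehicle-only genes. Equal enrichment over background gave a share difference of 9.92 (exact p = 0.200), 276 genes (exact p = 0.771), 46 stressed-only regions, 5 stressed-only and 6 vehicle-only genes, 0 lists at gene ends and 2 in distal regions. With background as covariate the share difference was 2.97 (exact p = 0.0857), and 3 lists passed in distal regions. With signal contrast as covariate it was 2.37 (exact p = 0.143) and the gene difference 1318 (exact p = 0.114). The 4 libraries with short lists, where p cannot go below 0.333, gave a share difference of 3.52, a gene difference of 1372, 2532 stressed-only and 1360 vehicle-only regions, 572 and 60 such genes and 0 lists. The 3 libraries with long lists, where the smallest p is also 0.333, gave 2.64, 865, 3284 and 3794, 706 and 86 and 0, with a similarity difference of -0.00559; fewer libraries make complete separation easier. Distal regions of the integrated stress response passed the unadjusted threshold in equal lists of 16414 regions (0.456 per 1000 more), within 20 kb (0.540) and at equal enrichment (0.568), all with an exact p of 0.0286.

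Leaving out 1 library ends each call by construction, since the smallest p is then 0.100 or 0.0667. The share difference ranged from 2.33 to 3.84, the gene difference from 1046 to 1545, stressed-only regions from 591 to 1440, vehicle-only regions from 269 to 856, stressed-only genes from 128 to 385 and vehicle-only genes from 4 to 18, with 0 lists at gene ends. Without vehicle 8 the stressed-only regions numbered 1440 and the genes 385, and without vehicle 7 the vehicle-only regions numbered 856. Differentiation numbers 6, 7 and 8 occur in both treatments. With the number as a replicate block, whose smallest p is 0.250, the share difference was 3.17, the gene difference 1249, 0 lists passed and the stressed-only regions of 3 pairs numbered 737. Libraries of the same number did not deviate together (correlations across consensus regions of -0.0548, -0.0968 and -0.127), and no library correlated best with its own number. Over all results, of 2124 values under alternatives, 3 values that were called in 1 of the settings reversed and 77 changed sign with or without a call, and of 703 values for gene lists 579 stayed on the same side and in the same direction.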

Other observations

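The tests of depth, signal contrast, treatment on chromosome X, the splits of the libraries for the region and gene counts and for the integrated stress response regions, and the enrichment of lists among group-specific regions were chosen after the results were seen. Beyond the named comparisons, several gene groups had members open in a larger share of the stressed libraries whose list did not pass. Among the progenitor and proliferation markers, MKI67 and HES1 had a region at an end in 4 stressed and 1 vehicle libraries and SOX2 in 4 and 2. Among the genes of respiration, NDUFA9 was open in 4 and 1 and CYC1, SDHB and COX5A in 4 and 2. Of the genes of lysosomes and the unfolded protein response, LAMP1 and ERN1 were open in 4 and 1. In the autophagy and lysosome list 5 members were open in a larger share of the stressed libraries and 3 in a larger share of the vehicle libraries. The gain of that list stood at percentile 8.2 among the matched random lists. In the equal-size lists the dopaminergic transcription factor genes LMX1A and FOXA2 had the opposite direction, in 0 stressed and 1 vehicle libraries. GAD2 did too, in 2 and 3. In the deposited lists the counts were 2 and 2 for LMX1A, 3 and 2 for FOXA2, and 3 and 3 for GAD2. The 0 therefore gives a lower rank and not a closed gene end. These genes were chosen after their values were seen.

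Stressed-only regions lay near integrated stress response genes more often than other consensus regions. Of the 427 stressed-only regions within 100 kb of a gene end, 6 were nearest to a gene of this list, against 87 of 47999 consensus regions, an odds ratio of 8.36 (Fisher's exact test across regions, p = 1.32e-04, adjusted p = 0.00500 over 19 lists and both directions). Counted by gene, 4 of 29 list genes with a region had one, against 402 of 16004 other genes (Fisher's exact test across genes, p = 0.00583, not adjusted over lists). Of the 35 splits of the libraries, 1 gave as many such regions, the treatment split itself, and the highest other split gave 2. The treatment split also stood alone for oxidative stress genes (3 regions, highest other 1) and Parkinson disease genes (1 region, highest other 0). As a share of all stressed-only regions, however, the 6 regions were 1.23%, and 2 of the 35 splits reached that, the other with 2.5%. With so few regions an arbitrary division of the libraries is not excluded as the source. Of 10000 random gene sets with similar numbers of regions per gene, 2 held as many (permutation p = 0.0003, with the list itself counted as a set, not adjusted over lists), which argues against a general gain around genes with many regions. Without SLC7A5, which holds 3 of the 6, the one-sided Fisher's exact test across regions gave p = 0.0310 on 3 regions. This passed the unadjusted threshold, but 3 regions are a thin base and the list had the lowest p of all lists in the same data. Whether 1 locus carries the pattern therefore stays open. Whether chromatin near genes of this list opens with the treatment stays open, since the regions are few under each alternative: against 6 of 488 stressed-only regions, 2 of 296 in the deposited lists, 2 of 244 in equal lists of 16414 regions, 2 of 46 at equal enrichment over background and 1 of 33 with −log10 q of at least 5, a lower share in the first 2 and a higher one in the last 2.

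More gene ends were open in the stressed libraries, by 1260 genes. With log2 background, a measure of depth, as a covariate 741 genes remained (SE 209, exact permutation p = 0.0286). The simulation with no change gave a difference of 234 genes. Neither excludes depth, since a linear term over 7 libraries may adjust only in part and the simulation used the same regions in each library. Signal contrast, the median enrichment of the 5000 strongest regions over background, was 51.8, 29.5, 27.0 and 22 in the stressed libraries and 48.8, 31.1 and 58.6 in the vehicle libraries (exact permutation p of the log2 values = 0.229). With it as a covariate the term was 1318 genes, its SE rose from 336 to 437, and the call was lost because 4 of the 35 assignments gave a term as large (exact permutation p = 0.114), so with 7 libraries the part of contrast cannot be told apart from that of treatment. The share at gene ends lost its call with either covariate: from 3.13 percentage points (SE 0.889) it went to 2.97 with background (SE 1.25, exact permutation p = 0.0857), where 3 assignments gave a term as large, and to 2.37 with contrast (SE 0.911, exact permutation p = 0.143), where 5 did, so for the share both depth and contrast stay open. At equal enrichment over background the difference was 276 genes (exact permutation p = 0.771), while the share at gene ends differed by 9.92 percentage points (exact permutation p = 0.200), so the 2 measures moved apart. List length was not equal in this setting. The weakest region of the equal-size list lay below the cut of 8.18 in stressed 7 (6.84) and stressed 9 (6.67). It lay well above the cut in stressed 6 (12.4), vehicle 6 (12.2) and vehicle 8 (14.6). A response of gene ends to mitochondrial stress therefore stays open beside depth, contrast and the width of regions, and GC content was not tested.

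Weak regions, those beyond the equal-size list, were concentrated on chromosome X in all 6 libraries that had them, most in the 3 long lists. Their share on X was 3.03 times the share in the equal-size list in stressed 6, 3.65 times in stressed 7 and 2.40 times in vehicle 8, while the highest autosome reached 1.35, 1.16 and 1.47 times in these lists. In stressed 8, stressed 9 and vehicle 6 the share of weak regions on X was 1.64, 2.05 and 1.93 times that in the equal-size list. Treatment is not the whole cause, since the lowest ratio of a vehicle library with weak regions was the 1.93 of vehicle 6; the stressed libraries had 0.294 percentage points more weak regions on X (exact permutation p = 0.867 over 6 libraries), in a test whose smallest p, 0.0667, could not reach the threshold, so a difference in degree stays open. Random excursions of a raised background predicted that weak regions on X recur in another long list no more often than autosomal ones, and they did recur less often, by up to 13.8 percentage points (X minus autosomes -13.8). Yet they recurred at least 3.20 times as often as the same regions moved by 1 Mb, which random positions forbid. What sets these positions apart was not tested.

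The counts of completely separated regions were not exceptional. Of the 35 splits, 4 gave at least 488 regions present in all of 4 libraries and none of the other 3, with a highest other count of 652, and 6 gave at least 231 in the opposite direction, with a highest of 913. That highest split set stressed 8, stressed 9, vehicle 6 and vehicle 7 against the 3 libraries with long lists, which points to a structure by list length; within the 4 short and the 3 long lists the counts were 2532 and 1360, and 3284 and 3794. Chance can therefore not be excluded for these counts. For genes, 1 of 35 splits reached 115 in all of the 4 libraries and none of the 3, with a highest other count of 111. In the opposite direction 26 of 35 splits reached 3, with a highest of 88. The 111 genes and the 652 regions came from the same split, of stressed 6, stressed 7, stressed 9 and vehicle 8 against the other 3. Those 4 libraries had the highest background (1.43 to 5.99, the others 0.492 to 0.816), so a split by depth came close to the gene count of the treatment split. The 4 gene lists at an exact permutation p of 0.0286 for gene ends were reached by 1 of 35 splits, the next having 2. For distal regions the treatment split gave 0 lists and the highest other split 5; all 35 splits reach a count of 0, so this comparison decides nothing.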
